A study of Arabidopsis thaliana with 24 samples.

How the data were processed

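Transcript levels were measured by paired-end RNA sequencing of whole Arabidopsis thaliana seedlings of the Col-0 background grown on MS medium. Per the labels, the genotypes were wild type (WT) and the lines uap1-1 and uap1-2, both mutants of UAP1, and each was kept under control conditions or placed at 4 °C for 24 h. Each of the 6 groups had 4 libraries, 24 in all. The labels disagree on age: the design text gives 11 days before the treatment and 12 days at harvest, and the extraction protocol gives 10-day-old seedlings. Per the labels' protocols, RNA was selected with oligo(dT), fragmented and copied with random hexamers. The strand setting of the library and of the counting is not given in the sources used here, so a gene and an overlapping gene on the opposite strand cannot be separated.

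The authors deposited one table of 32833 genes with a read count and an FPKM value per gene and library. The submitters' processing notes name bcl2fastq 2.20.0.422, FastQC 0.10.1, cutadapt 1.9.1, HISAT2 2.2.1, StringTie 1.3.3b, SAMtools 0.1.19, HTSeq 0.6.1, DESeq2 1.26.0 and the genome build TAIR10, with no role or order. The deposited counts are whole numbers, not normalized. The deposited FPKM values equalled the count divided by the exonic length and the library total, with a highest difference of 0.005, so they carry no further scaling between libraries. Gene positions are those of the deposited table on TAIR10; 32548 loci were found in the reference annotation used here, 99.9% of them with the same start and end. There were 0 entries without a gene name. Counts per gene cannot measure splicing, and no gene carries the name UAP1 in the table or the annotation, so no check of the mutated gene was made.

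The groups, the tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. That plan foresaw limma on log2(FPKM + 1), with a count test if counts were deposited; since they were, the count test was used. Genes were kept by edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15, which left 21428 genes. Libraries were scaled by TMM, and 6 group means were fitted to all 24 libraries with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3. The p-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 was called. Fold changes are log2 values of edgeR's fit with its prior count of 0.125, and log2 CPM values, used for principal components and list scores, had a prior count of 2. The standard errors (SE) of fold changes were taken as the size of the fold change over the square root of the F statistic. The group levels are CPM (read counts scaled to a common library total) after TMM scaling, with the SD over 4 libraries.

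The contrasts were cold against control within each genotype, each mutant against WT in each condition, the difference of each mutant's cold response from that of WT, and uap1-2 against uap1-1 in each condition. A contrast of all mutant against all WT libraries was added after the data had been seen. On simulated counts over the same 21428 genes with 200 changed, the test of uap1-1 against WT under control conditions recovered 7.46% of 1.5-fold, 46.3% of 2-fold and 83.3% of 4-fold changes, and 4.21% of its calls were false. For uap1-2 against WT in the cold these shares were 4.48%, 55.2% and 84.8%, with 7.69% false, and for cold in WT 8.96%, 59.7% and 81.8%, with 8.26% false. Genes were drawn independently of one another, so these shares leave out variation that many genes share within a group. With 200 changed genes they also do not describe the measured cold comparisons, where far more genes changed.

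There were 20 gene lists with 298 entries at 297 loci, of which 286 entries were measured: CBF and first-wave cold transcription factors, COR genes, upstream cold signalling, ABA and dehydration, circadian clock, light harvesting and carbon fixation, flavonoid and anthocyanin synthesis, heat shock proteins, salicylic acid and immunity, jasmonate, SR splicing proteins, spliceosome and associated factors, cold-related RNA-binding proteins, growth and auxin, sugar and starch, cell cycle, root markers, seed and embryo markers, floral markers and reference genes. The 19 lists with at least 5 measured members were tested as sets with camera (limma 3.58.1), with its preset correlation and again with a correlation estimated from these libraries, and adjusted over the lists of a comparison. List scores, the mean log2 CPM of a list in a library, were compared by a two-sided exact permutation test of 4 against 4 libraries, whose smallest possible p is 0.0286. These p-values were adjusted over all lists and genotypes of the cold effects together, and likewise over all comparisons of a mutant with WT. KEGG pathways of at least 10 tested genes, from the annotation in the deposited table, were tested in the same way after the data had been seen.

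The named genes are up to 4 members per list and comparison with the smallest adjusted p, 7 cold genes named throughout (CBF1, CBF2, CBF3, COR15A, COR47, KIN1 and RD29A), and, per comparison, the 5 called genes with the highest and the 5 with the lowest fold change that had a mean FPKM of at least 2 and no overlap between the groups. Where a comparison called few genes, they are named as well. A fold against a group at 0 counts is given as a lower bound from a floor of 3 counts over the group, and with 1 to 3 counts as a ratio of counts per library size with its exact 95% interval. Library totals ran from 19289385 to 25501547 counts. Read counts carry no molecular identifiers, so intervals of ratios and floors cover counting error only.

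The replicate numbers of the labels were checked as a possible pairing. Of the 15 pairs of groups, 1 had a correlation over 0.1 for every same-numbered pair of libraries (uap1-1 with uap1-2 in the cold, 0.50, 0.54, 0.23 and 0.31), over deviations from the group means; over all pairs the correlation ran from -0.53 to 0.54. That pairing comes from the data, since no label speaks of a shared batch. The alternatives were DESeq2 1.42.0, limma on log2(FPKM + 0.1), log2(FPKM + 1) and log2(FPKM + 5), quantile normalization, other filters, other scalings, nuclear genes alone, library weights, robust moderation, a replicate block, a 2-fold threshold, fits of fewer libraries, a length correction, a covariate and leaving out each library in turn.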

Results

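Gene expression was measured in seedlings of WT, uap1-1 and uap1-2 under control conditions and after 24 h at 4 °C, with 4 libraries in each of the 6 groups. The series title presents UAP1 as a splicing factor that takes part in responses to cold stress. The labels call the libraries of a group independent biological replicates. Library totals ran from 19786138 to 22860484 counts in WT control and 19343461 to 23903456 in WT cold. They ran from 19376003 to 21406990 in uap1-1 control, 19322222 to 25501547 in uap1-1 cold, 19545075 to 24917449 in uap1-2 control and 19289385 to 23377361 in uap1-2 cold. The 10 most abundant genes took 5.93% to 11.9% of a library. Every pair of replicates differed by more than sampling noise, with a chi-square statistic per degree of freedom of 8.95 to 154 over 36 pairs. Cold and control libraries lay apart on the first principal component, which held 65.1% of the variance. On that component the genotypes overlapped within each condition, except for WT (-97.6 to -88) and uap1-2 (-87.6 to -67.2) in the cold.

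**Figure D1:**
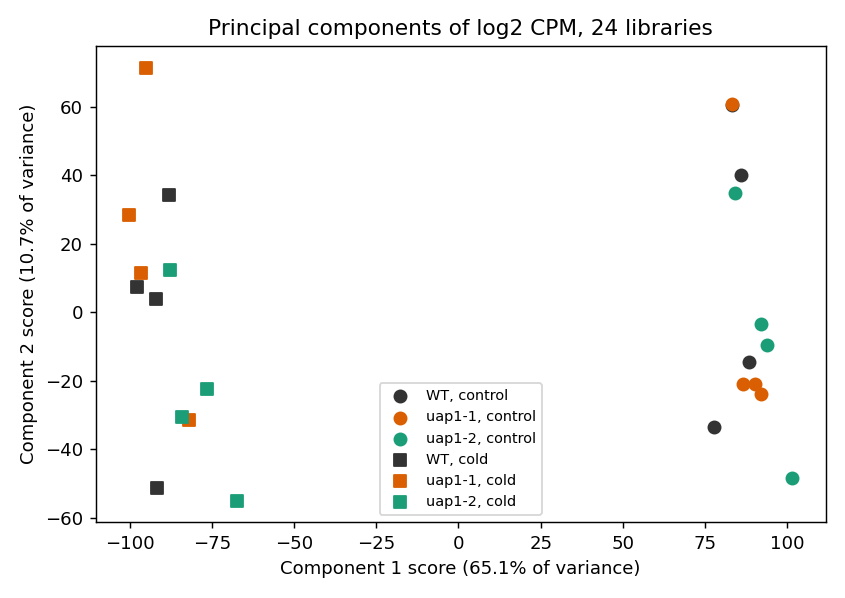
Scores of the 24 libraries on the first and second principal components of log2 CPM, with 65.1% and 10.7% of the variance on the horizontal and vertical axes. Colours show genotypes, circles control and squares cold; all control libraries have positive and all cold libraries negative scores on component 1.

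The first question was how WT seedlings responded to cold. The CBF genes, which encode transcription factors that switch on cold-induced genes, were higher after 24 h at 4 °C. CBF1 (AT4G25490, chromosome 4, 13021780 to 13022996, minus strand) went from 1.33 ± 0.869 to 6.45 ± 2.81 CPM (SD, n = 4). CBF2 (AT4G25470, chromosome 4, 13015250 to 13016235, minus strand) went from 4.76 ± 3.2 to 56.8 ± 20.4 CPM, and CBF3 (AT4G25480, chromosome 4, 13018010 to 13019400, minus strand) from 20.2 ± 5.34 to 115 ± 26.6 CPM. Their log2 fold changes were 2.29 (SE 0.47), 3.59 (SE 0.49) and 2.51 (SE 0.21), with adjusted p = 0.000262, 1.68e-06 and 9.36e-10 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The COR genes, targets of the CBF factors that protect cells in the cold, rose further. COR15A (AT2G42540, chromosome 2, 17710441 to 17712330, minus strand), which encodes a chloroplast protein that stabilises membranes, rose from 594 ± 217 to 8380 ± 1520 CPM, and the dehydrin gene COR47 (AT1G20440, chromosome 1, 7084409 to 7086873, minus strand) from 592 ± 112 to 9150 ± 124 CPM. KIN1 (AT5G15960, chromosome 5, 5209717 to 5210826, plus strand) rose from 37.9 ± 15.3 to 1310 ± 120 CPM, and RD29A (AT5G52310, chromosome 5, 21240717 to 21243644, plus strand) from 620 ± 123 to 15000 ± 2520 CPM. In the genome, 6.91%, 11% and 2.57% of the 31-base words of CBF1, CBF2 and CBF3 and 5.56% of those of KIN1 occur elsewhere. An annotated gene on the opposite strand (AT4G07385) overlaps CBF3. The levels of these genes are uncertain to the extent that reads of the copies or of that gene were counted with them.

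**Figure D2:**
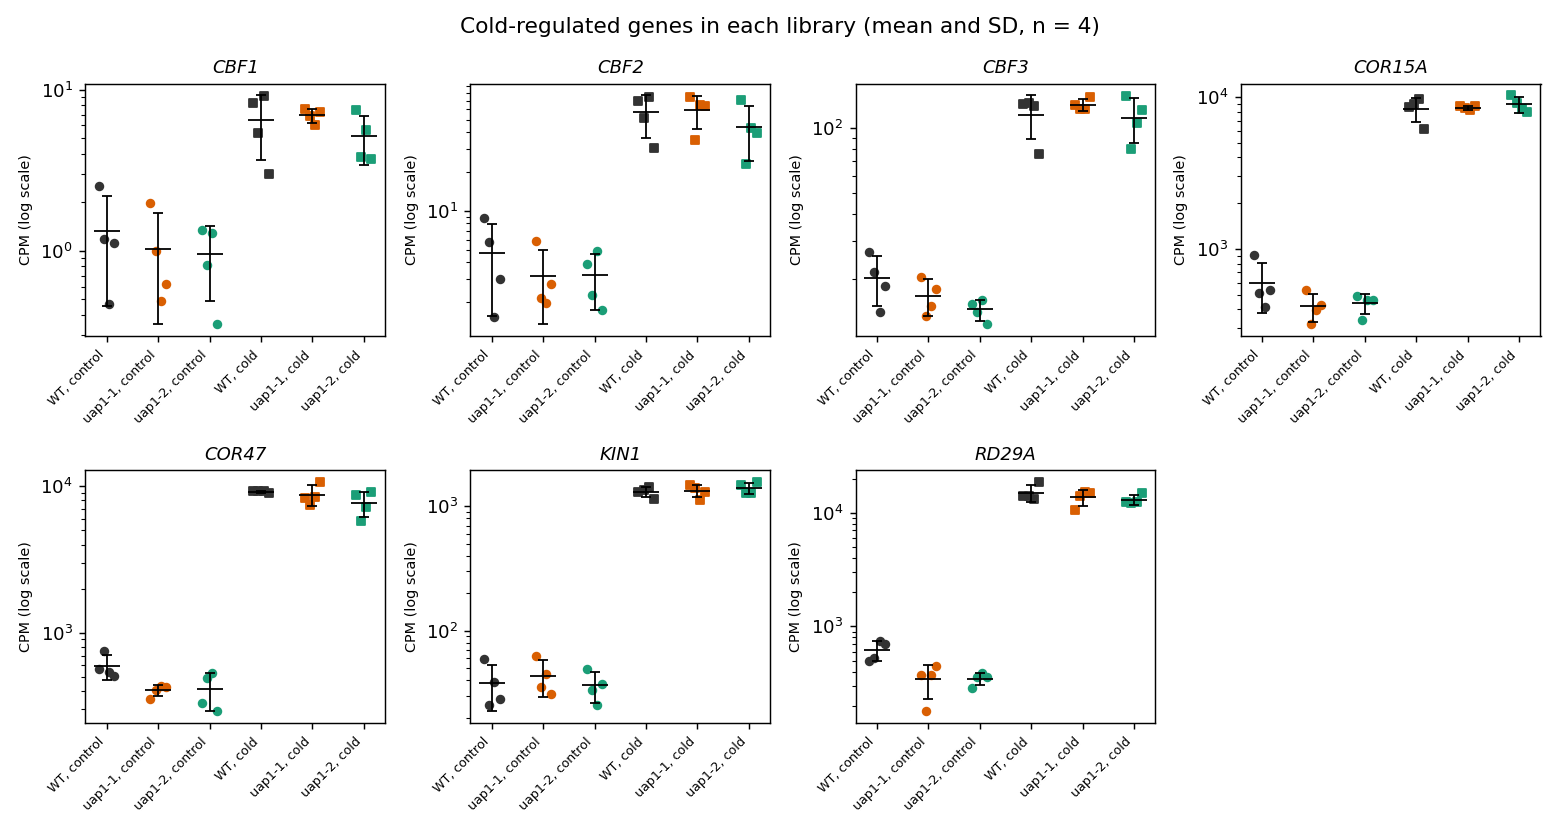
CPM of CBF1, CBF2, CBF3, COR15A, COR47, KIN1 and RD29A in each library on log axes, with group means and SD bars (n = 4); colours show genotypes, circles control and squares cold. Each gene lies higher in the cold groups of all genotypes, for example KIN1 at 37.9 ± 15.3 CPM in WT control and 1310 ± 120 CPM in WT cold.

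In all, 11619 of 21428 genes changed in WT, 5528 higher and 6091 lower in the cold, and 6561 of them at least 2-fold (edgeR quasi-likelihood, Benjamini-Hochberg). The balance of directions depended on scaling: with library totals in place of TMM, 4109 of 11615 calls were higher and the median log2 fold change of all genes moved from -0.06 to -0.27. All 13 measured members of the list of CBF and first-wave transcription factors rose, with RAP2.6 at 4.49, RAP2.1 at 4.45 and ZAT6 at 4.42 on the log2 scale. The set test passed at adjusted p = 0.0452 with an estimated correlation, but not without WT control replicate 1, 2, 3 or 4 (adjusted p = 0.0517, 0.0522, 0.0708 and 0.0597). Of 16 COR genes, 15 rose, and 16 when adjusted over the list alone (adjusted p = 4.47e-07 with an estimated correlation). The early light-induced protein genes ELIP2 (AT4G14690) and ELIP1 rose by 10.54 (SE 0.36) and 8.75 (SE 0.28), and the dehydrin XERO2 by 6.62 (SE 0.27). In the sugar and starch list, 7 of 11 rose and 2 fell (adjusted p = 0.000287 with an estimated correlation). Those that rose included the galactinol synthase GOLS3 at 8.33, the sucrose synthase SUS1 at 5.13, the starch-degrading BAM3 at 5.09 and the starch synthase GBSS1 at 4.41, while MEX1 was at -0.87 and DPE2 at -0.50. Flavonoid and anthocyanin genes rose in 18 of 20 cases and 1 fell (adjusted p = 0.000457 with an estimated correlation). The biosynthetic genes F3H at 6.58, FLS1 at 5.11, CHI at 5.03 and 4CL3 at 4.2 rose, and MYBL2, a repressor of the pathway, fell by 1.13. In the clock list, 14 of 19 rose and 1 fell (adjusted p = 0.00224 with an estimated correlation). The morning factors LHY, CCA1, RVE1 and RVE8 rose by 7.38, 6.15, 5.27 and 4.23, and PRR3 fell by 1.47. Counts adjusted over the list alone equalled those over all genes for every list of this comparison except the COR genes and the root markers.

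For other lists the genes moved without a set call that held with an estimated correlation. In the ABA and dehydration list 18 of 19 rose, at adjusted p = 0.205 with an estimated correlation. Among them were, with log2 fold changes, CYP707A1, which encodes an ABA-degrading enzyme (3.78, SE 0.29), RD26 (3.47), RD20 (2.84) and the phosphatase HAB1 (2.79). All 10 heat shock genes rose, HSP17.6II by 7.02 (SE 0.57), HSP70 by 4.89, HSP90.1 by 4.16 and HSP101 by 3.39 (adjusted p = 0.152 with an estimated correlation, or 0.0452 without WT cold replicate 3). Of 21 genes of light harvesting and carbon fixation, 16 fell (adjusted p = 0.46 with an estimated correlation). The antenna genes LHCB4.2, LHCB1.4, LHCB2.3 and LHCB2.2 stood at -3.47, -3.28, -2.63 and -2.51. In the growth and auxin list 6 of 12 fell, with the expansins EXPA8 at -5.79, EXPA1 at -1.95 and EXPA11 at -1.87 and PRE1 at -3.44 (adjusted p = 0.52 with an estimated correlation). Upstream cold signalling went both ways, 6 up and 6 down of 20. PIF4, which encodes a growth-promoting transcription factor, fell by 2.81, and PIF7 rose by 2.04, the kinase gene OST1 by 1.98 and ICE1, an activator of CBF genes, by 0.93.

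Genes of RNA processing also changed in both directions in WT. Of 20 SR splicing protein genes, 9 rose and 7 fell, with SCL30A at a log2 fold change of 1.48 (SE 0.16) and RS2Z32 at 1.00 against SCL33 at -1.76 (SE 0.16) and RSZ21 at -1.43. Of 28 spliceosome genes 10 rose and 4 fell, including STA1 at 1.1, U1C at 0.96, CBP80 at 0.95 and PTB1 at 0.67. Of 13 RNA-binding proteins 5 rose and 1 fell, with CSP1 at 1.39, CSP3 at 0.78, UBP1B at 0.63 and UBP1C at -0.63. None of these 3 lists passed the set test, which compares a list with the other genes (adjusted p = 0.816, 0.121 and 0.859 by camera). Their mean log2 CPM scores differed between cold and control by 0.05, 0.31 and 0.15. The spliceosome score was higher in all cold libraries of WT, uap1-1 (0.29) and uap1-2 (0.22), as were the SR and RNA-binding scores of uap1-1 (0.26 and 0.39). All of these had two-sided exact permutation p = 0.0286 and adjusted p = 0.0464. The reference gene score rose by more than the spliceosome score, by 0.34 in WT, 0.58 in uap1-1 and 0.34 in uap1-2, with no overlap in WT alone. The shift is thus not particular to spliceosome genes. With library totals 0 of 20 list scores passed in each genotype. COR genes in WT also missed (adjusted p = 0.0536, exact permutation test), so this is not particular to these lists. Their score still differed by 4.19, at the smallest possible p of 0.0286 by that test. The adjustment was over the scores of all 3 genotypes together. Whether a separated list passed thus depended on how many other lists were separated. With library totals the spliceosome differences were 0.12, -0.13 and 0.03, and the SR and RNA-binding differences of uap1-1 were -0.16 and -0.03. The salicylic acid list had 4 genes up and 6 down of 15, with CBP60G at 2.88, PR5 at 2.82, NIMIN1 at -3.46 and SAG101 at -1.18. The jasmonate list had 2 up and 3 down of 11, with JAZ1 at 2.77, JAZ5 at 1.67, VSP2 at -2.51 and LOX2 at -0.87. Among cell cycle genes 1 of 10 fell (CYCA2;3, -1.23). Among root markers 2 of 12 rose (IRT1 at 1.58 and SCR at 0.62), 1 of them when adjusted over the list alone. The call of IRT1 was lost without WT cold replicate 1 or 4 (adjusted p = 0.0788 and 0.0898) and without WT control replicate 3 or 4 (adjusted p = 0.0822 and 0.0923), and that of SCR with library totals (adjusted p = 0.0582), each by edgeR. Of 5 floral markers 0 passed edgeR's test, and 3 of 8 reference genes rose (GAPC1 at 1.41, EF1A at 0.65 and SAND at 0.31). SAND lost its call without WT cold replicate 1 (adjusted p = 0.0563) or WT control replicate 2 (adjusted p = 0.0632) and with library totals (log2 0.10, adjusted p = 0.609), each by edgeR. The seed markers OLEO1 (3 and 83 counts over the group, a ratio of 30.1 with a 95% interval of 9.96 to 149) and EM6 (3.54, SE 0.77) rose, 2 of 3 measured. The largest rises were those of AT4G27360 (at least 990-fold higher), AT1G26790 (at least 436-fold), AT3G09590 (at least 178-fold), UGT78D3 and ELIP2. UGT78D3 (AT5G17030), a flavonoid glycosyltransferase gene, had a ratio of 2590 with an interval of 886 to 12600. The largest falls were those of AT1G12805 (a ratio of 231, interval 63.7 to 1920), AT3G29370 (197, 54.3 to 1640), AT4G34790 (129, 35.4 to 1070), AT1G33055 (log2 -6.46) and AT2G29300 (log2 -6.14).

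Cold was then examined in uap1-1, to see whether the same gene groups responded. CBF1 rose from 1.03 ± 0.679 to 6.94 ± 0.688 CPM, CBF2 from 3.18 ± 1.84 to 59.3 ± 17.1 and CBF3 from 16.7 ± 3.19 to 128 ± 8.08 CPM (SD, n = 4). Their log2 changes were 2.76 (SE 0.48), 4.22 (SE 0.50) and 2.93 (SE 0.21). COR15A reached 8510 ± 280 CPM from 418 ± 88.2, COR47 8720 ± 1380 from 405 ± 35.2, KIN1 1330 ± 154 from 43.5 ± 14.3 and RD29A 13700 ± 2110 from 341 ± 114. In the lists, 13 of 13 first-wave factors (RAP2.1 at log2 5.36, ZAT6 at 4.98, CZF1 at 2.34) and 16 of 16 COR genes (ELIP2 at 9.53, ELIP1 at 8.13, XERO2 at 6.30) rose, with adjusted p = 0.0343 and 5.34e-07 with an estimated correlation. The set of first-wave factors missed the threshold without uap1-1 control replicate 2 (adjusted p = 0.0501). Sugar and starch genes had 8 up and 2 down of 11 (GOLS3 at 8.69, SUS1 at 5.27, BAM3 at 5.19, GBSS1 at 4.75). Flavonoid genes had 15 up and 0 down of 20 (CHI at 4.93, FLS1 at 4.28, 4CL3 at 4.1, PAL2 at 3.83; 17 up when adjusted over the list alone), and clock genes had 14 up and 1 down of 19 (LHY at 7.29, CCA1 at 5.93, RVE1 at 5.39, RVE8 at 4.19). These 3 sets had adjusted p = 7.04e-05, 0.000993 and 0.00317 with an estimated correlation. ABA genes rose in 18 of 19 cases (RD26 at 4.56, NCED3, which makes ABA, at 3.56, RD20 at 3.51, HAB1 at 3.36). Heat shock genes rose in 10 of 10 (HSP17.6II at 6.98, HSP70 at 5.38, HSP90.1 at 4.18, HSP101 at 3.17). These lists had adjusted p = 0.0903 and 0.096 with an estimated correlation. Of 21 light-harvesting genes 8 fell (LHCB4.2 at -2.83, LHCB1.4 at -2.19, LHCB2.3 at -1.71, LHCB2.2 at -1.57) and LHCB1.1 rose by 1.18 (adjusted p = 0.771 with an estimated correlation).

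The RNA processing lists of uap1-1 had 10 SR genes up and 5 down of 20 (SCL30A at log2 1.66, RS2Z32 at 1.16, SC35 at 1.11, SCL33 at -1.49). They had 13 spliceosome genes up and 2 down of 28 (13 and 3 when adjusted over the list alone; U1C at 1.19, STA1 at 1.19, SKIP at 0.83, PTB1 at 0.82), and 5 RNA-binding protein genes up and 0 down of 13 (CSP1 at 1.55, UBP1B at 1.25). In upstream signalling 8 rose and 4 fell of 20 (PIF4 at -2.51, PIF7 at 1.88, OST1 at 1.81, ICE1 at 1.22). In growth and auxin 6 of 12 fell (EXPA8 at -6.20, PRE1 at -4.32; adjusted p = 0.557 with an estimated correlation). In the salicylic acid list 4 rose and 4 fell of 15, 5 falling when adjusted over the list alone (CBP60G at 2.91, PR5 at 2.70, EDS1 at -1.07). Jasmonate genes had 2 up and 3 down of 11, or 1 and 3 over the list alone (JAZ1 at 2.82, VSP2 at -1.94). Cell cycle genes had 2 of 10 down (CYCA2;3 at -1.32), root markers 1 up and 2 down of 12 (SCR at 0.72, MYB36 at -1.51; 1 and 1 when adjusted over the list alone). With library totals SCR stood at 0.29 (adjusted p = 0.153, edgeR). Floral markers had 1 of 5 up (AP1 at 1.83; 0 over the list alone). Without uap1-1 cold replicate 2 AP1 stood at 0.73 (adjusted p = 0.421), and its call was also lost without uap1-1 control replicate 2 or 4 (adjusted p = 0.0968 and 0.0837) and with library totals (adjusted p = 0.115), each by edgeR. Seed markers had 2 of 3 up (EM6 at 3.32) and reference genes 6 of 8 up (GAPC1 at 1.53, EF1A at 1.01; 6 up and 1 down over the list alone), of which SAND and UBC21 were not called with library totals (adjusted p = 0.379 and 0.0939, edgeR). RHD6, a root marker at -1.20, lost its call without uap1-1 cold replicate 2, 3 or 4 or uap1-1 control replicate 1, 3 or 4 (adjusted p of 0.0517 to 0.106), and the jasmonate gene OPR3 without uap1-1 cold replicate 2 or 4 or uap1-1 control replicate 2 or 4 (adjusted p of 0.0533 to 0.0965). For the other lists of this comparison the counts adjusted over the list alone were the same as those over all genes. The rises were led by UGT78D3 (log2 10.37, SE 0.48), AT4G27360 (log2 9.80, SE 0.44), AT3G09590 (at least 174-fold), AT1G19500 (at least 124-fold) and ELIP2. The falls were led by AT1G12805 (at least 270-fold), AT4G34790 (at least 74.8-fold), AT4G08505 (at least 37.8-fold), AT3G53250 (a ratio of 238, interval 42.4 to 9440) and AT1G68190 (log2 -6.51, SE 0.32). By edgeR with Benjamini-Hochberg adjustment 11971 genes changed, 5720 higher and 6251 lower, and 6783 of them at least 2-fold. With library totals, 3387 of 13132 calls were higher and the median of all genes moved from -0.07 to -0.50.

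In uap1-2, cold raised CBF1 from 0.952 ± 0.468 to 5.15 ± 1.76 CPM, CBF2 from 3.2 ± 1.45 to 44.2 ± 19.9 and CBF3 from 14.4 ± 1.59 to 112 ± 25.9 CPM (SD, n = 4). Their log2 changes were 2.43 (SE 0.48), 3.79 (SE 0.49) and 2.95 (SE 0.21). COR15A reached 8940 ± 1040 CPM from 439 ± 67.2, COR47 7690 ± 1490 from 412 ± 119, KIN1 1400 ± 148 from 36.5 ± 10.1 and RD29A 13000 ± 1360 from 347 ± 42.2. First-wave factors rose in 13 of 13 cases (RAP2.6 at log2 4.72, RAP2.1 at 4.57, ZAT6 at 4.25) and COR genes in 16 of 16 (ELIP2 at 10.35, ELIP1 at 8.39, XERO2 at 6.49), with adjusted p = 0.0265 and 2.1e-07 with an estimated correlation. Sugar and starch genes had 8 up and 1 down of 11 (GOLS3 at 8.49, SUS1 at 5.26, BAM3 at 5.14, GBSS1 at 4.54). Flavonoid genes had 17 up and 1 down of 20 (F3H at 5.74, CHI at 4.76, FLS1 at 4.65, PAL1 at 3.46) and clock genes 14 up and 1 down of 19 (LHY at 7.65, CCA1 at 5.90, RVE1 at 5.02, RVE8 at 4.55). These 3 sets had adjusted p = 5.03e-05, 0.000518 and 0.00236 with an estimated correlation. All 19 ABA genes rose (RD20 at 3.87, RD26 at 3.79, CYP707A1 at 3.73, HAB1 at 3.04), as did 10 of 10 heat shock genes (HSP17.6II at 7.18, HSP70 at 5.07, HSP90.1 at 3.91, HSP101 at 2.47). The lists had adjusted p = 0.11 and 0.121 with an estimated correlation. Of 21 light-harvesting and carbon fixation genes 17 fell (LHCB4.2 at -3.13, LHCB1.4 at -3.11, RBCS2B at -2.22, LHCB2.2 at -2.11; adjusted p = 0.472 with an estimated correlation).

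Among RNA processing genes of uap1-2, 8 SR genes rose and 7 fell of 20 (RSZ22a at log2 1.3, SCL30A at 1.19, RS2Z32 at 0.86, SCL33 at -1.88; 8 and 8 when adjusted over the list alone). In the other lists 8 spliceosome genes rose and 4 fell of 28 (CBP80 at 0.84, STA1 at 0.84, U1C at 0.71, PTB1 at 0.66), and 4 RNA-binding protein genes rose and 4 fell of 13 (CSP1 at 1.23, UBA2B at -0.46). Upstream signalling had 5 up and 5 down of 20 (PIF4 at -2.65, OST1 at 2.27, PIF7 at 2.1, ICE1 at 0.80), and growth and auxin 5 of 12 down (EXPA8 at -5.95, PRE1 at -3.34; 4 over the list alone; adjusted p = 0.55 with an estimated correlation). The salicylic acid list had 4 up and 5 down of 15 (PR5 at 3.09, CBP60G at 2.65, ICS1 at -1.19) and the jasmonate list 1 up and 2 down of 11 (JAZ1 at 3.13, VSP2 at -1.90). Cell cycle genes had 2 of 10 down (CYCA2;3 at -1.35; 1 over the list alone) and root markers 2 of 12 up (IRT1 at 2.35, SCR at 0.61). Seed markers had 3 of 3 up (OLEO1 at least 39.5-fold higher, EM6 at 2.50). Replicate 4 of uap1-2 cold had a seed marker score of 1.94 against -0.62 or lower in its group, and without it EM6 stood at 1.59 and was not called (adjusted p = 0.0874, edgeR). With library totals SCR missed the threshold (0.41, adjusted p = 0.0536, edgeR). Floral markers had 0 of 5 changed by edgeR's test and reference genes 2 of 8 up (GAPC1, and SAND at 0.62). CYCB2;4, the other cell cycle gene, was not called without uap1-2 cold replicate 1 or 4 or uap1-2 control replicate 1 or 4 (adjusted p of 0.0723 to 0.0934, edgeR). No other count of this comparison moved when it was adjusted over the list alone. The strongest rises were in UGT78D3 (log2 9.55, SE 0.47), AT1G26790 (a ratio of 1030, interval 184 to 40700), LEA46 (log2 9.28, SE 0.58), AT1G19500 (at least 88-fold) and ELIP2. Falls were strongest in AT4G34790 (at least 103-fold), AT3G53250 (a ratio of 300, interval 53.5 to 11900), AT1G33055 (173, 47.6 to 1430), AT1G12805 (163, 44.7 to 1350) and GASA6 (log2 -6.30, SE 0.46). By edgeR with Benjamini-Hochberg adjustment 11245 genes changed, 5682 higher and 5563 lower, and 6227 of them at least 2-fold. With library totals, 4198 of 11196 calls were higher and the median of all genes moved from -0.01 to -0.20.

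The cold responses of the 3 genotypes, which share no libraries, were set against one another. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.911 between WT and uap1-1, 0.945 between WT and uap1-2 and 0.909 between the mutants. In all 3 genotypes 4325 genes rose and 4370 fell, where independent lists would share 391 and 461. These made up 78.2% of the genes that rose in WT and 71.7% of those that fell, while 333 that rose and 554 that fell were called in WT alone; a call in 1 genotype alone is no test of a difference between genotypes. Opposite calls in any pair of genotypes occurred for 3 genes.

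**Figure D3:**
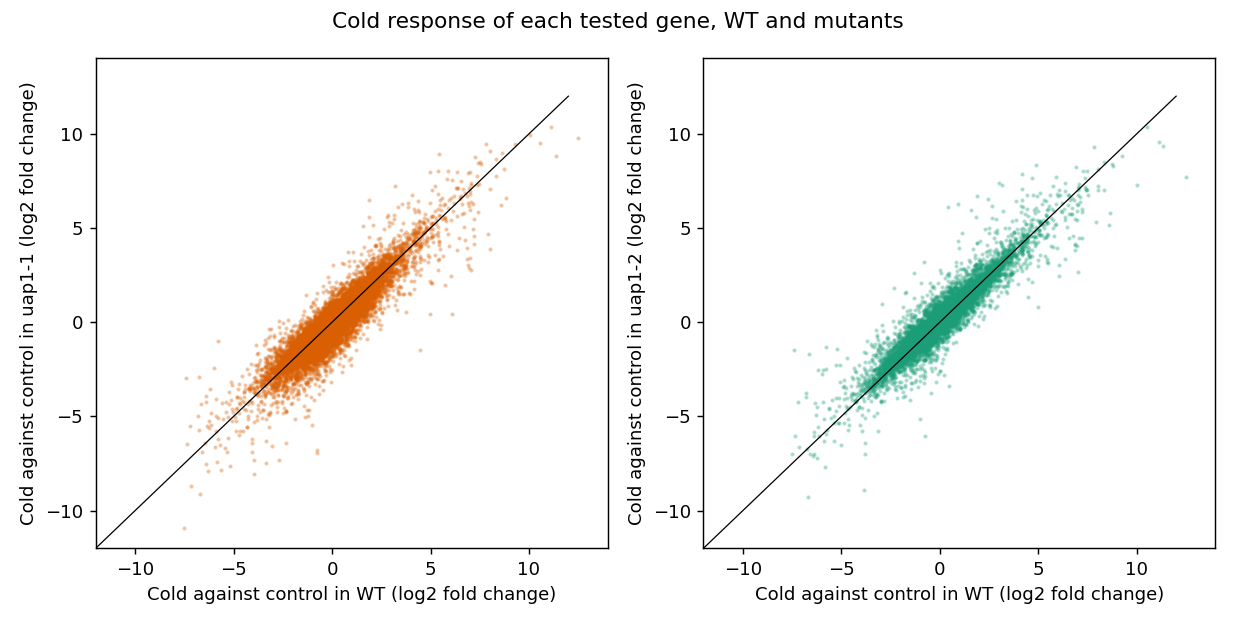
Cold against control log2 fold change of each of the 21428 tested genes in WT (horizontal) and in uap1-1 or uap1-2 (vertical, left and right panel), 1 point per gene; the line marks equal change. The points follow the line, with r = 0.911 for uap1-1 and 0.945 for uap1-2.

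Under control conditions uap1-1 was compared with WT to see which genes differed without stress. HAI1 (AT5G59220, listed as SAG113 in the deposited table; chromosome 5, 23894404 to 23896939, minus strand), which encodes a type 2C protein phosphatase of the ABA pathway, stood at 26.5 ± 9.51 CPM in WT and 2.61 ± 0.724 CPM in uap1-1 (SD, n = 4). Its log2 fold change was -3.34 (SE 0.43, 95% interval -4.23 to -2.45, adjusted p = 0.00165, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). The uap1-1 libraries lay between 1.67 and 3.25 CPM, all under the WT libraries. This was the 1 gene called, with 1961 genes at an unadjusted p under 0.05, where chance would give 1071 on average. In comparisons with 0 calls that number ran from 371 to 2368, so 1961 is no measure of an excess. DESeq2 called 31, limma on log2(FPKM + 5) 79 and a fit with library quality weights 325. EdgeR called 156 with the first within-group component as a covariate, which is taken from these libraries' own residuals and lowers their spread by construction. In the lists, ABA genes had a median log2 difference of -0.44 (2 lower when adjusted over the list alone), COR genes -0.39 (2 higher and 5 lower over the list alone), light-harvesting genes -0.44 with 0 of 21 estimates positive, and heat shock genes -0.61. Flavonoid genes stood at a median of 0.56 (10 higher and 1 lower over the list alone) and cell cycle genes at 0.29 with 10 of 10 estimates positive. Of the 19 lists, 12 passed camera with its preset correlation and 0 with an estimated correlation, where ABA, light-harvesting, heat shock and cell cycle genes each had adjusted p = 0.362 with an estimated correlation, COR genes adjusted p = 0.287 and flavonoid genes adjusted p = 0.0511. Flavonoid genes passed without WT control replicate 1 or uap1-1 control replicate 3 (adjusted p = 0.00371 and 0.032 with an estimated correlation). Single libraries carried a large part of other list values. Without WT control replicate 1 light-harvesting genes stood at -0.19 with 5 of 21 positive (difference of the list score, -0.16 in place of -0.38) and COR genes at -0.23. Without WT control replicate 3 cell cycle genes stood at 0.16 and the heat shock score differed by -0.30 in place of -0.52, and without uap1-1 control replicate 2 ABA genes stood at -0.29. With each library left out in turn, 1 to 5 ABA and 3 to 6 COR genes were lower and 3 to 10 flavonoid genes higher when adjusted over the list alone, and 8 to 10 cell cycle estimates were positive. Before cold, RD29A was at 620 ± 123 CPM in WT and 341 ± 114 in uap1-1 (log2 -0.86) and COR47 at -0.55, neither called over all genes by edgeR without a covariate. RD29A was called by DESeq2 (-0.85, adjusted p = 0.0382), with library quality weights (-0.66, adjusted p = 0.0349) and by edgeR with the covariate (-0.89, adjusted p = 0.0221).

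**Figure D4:**
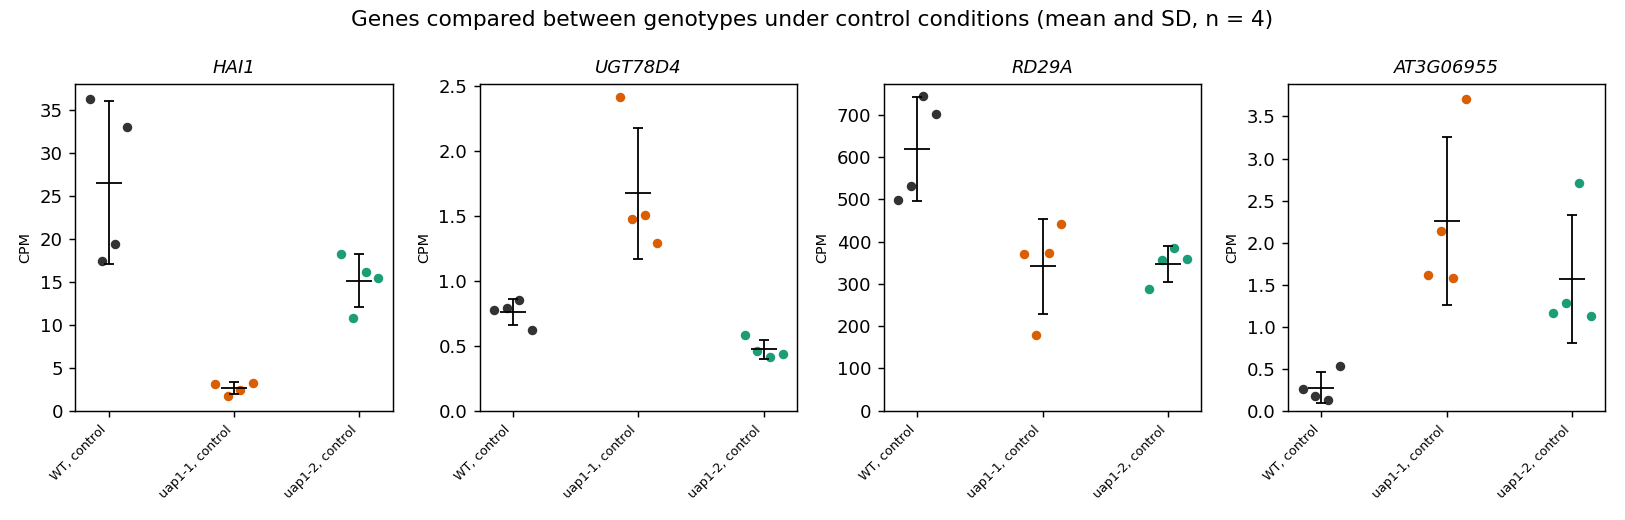
CPM of HAI1, UGT78D4, RD29A and AT3G06955 in each control library on linear axes from 0, with group means and SD bars (n = 4); colours show genotypes. HAI1 lies at 26.5 ± 9.51 CPM in WT and 2.61 ± 0.724 CPM in uap1-1, and UGT78D4 at 1.67 ± 0.504 CPM in uap1-1 and 0.474 ± 0.0734 CPM in uap1-2.

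For uap1-2 under control conditions, edgeR called 0 genes against WT, with 1152 at an unadjusted p under 0.05 and a smallest adjusted p of 0.431; DESeq2 called 13 and edgeR with the covariate 3. HAI1 was at 15.1 ± 3.12 CPM (SD, n = 4), a log2 difference of -0.81 with adjusted p = 0.865 by edgeR's quasi-likelihood test. As sets, COR genes (median -0.45, 1 higher and 7 lower when adjusted over the list alone) and sugar and starch genes (median -0.29, 0 higher and 2 lower over the list alone) were lower, both at adjusted p = 0.0305 with an estimated correlation and among 10 lists that passed with the preset correlation. These calls rested on single libraries. With each library left out in turn, COR genes passed in 3 of 8 fits and not without WT control replicate 1 or 3 or uap1-2 control replicate 2, 3 or 4 (adjusted p of 0.0518 to 0.129). Sugar and starch genes passed in 2 of 8, and not without those libraries or WT control replicate 4 (adjusted p of 0.0518 to 0.154). The COR median was -0.16 without WT control replicate 1, and from 0 to 8 COR genes and 0 to 5 sugar and starch genes were lower over the list alone. The COR list score differed from WT by -0.31, with libraries of both groups overlapping (two-sided exact permutation p = 0.0571, adjusted p = 0.653). RD29A, at 347 ± 42.2 CPM, had a log2 difference of -0.84 and COR47 of -0.52. ABA genes had a median of -0.42, heat shock genes -0.88, light-harvesting genes -0.32 with 0 of 21 positive and cell cycle genes 0.38 with 10 of 10 positive. Their adjusted p = 0.307, 0.259, 0.407 and 0.307 with an estimated correlation. The light-harvesting value rested on WT control replicate 1, without which the median was -0.02 with 10 of 21 positive and the score difference -0.01 in place of -0.23. Heat shock genes stood at -0.55 without WT control replicate 3 and -1.51 without uap1-2 control replicate 3. Cell cycle genes stood at 0.24 without WT control replicate 2, and at 0.21 and 0.61 without uap1-2 control replicate 1 or 3. HAI1 is a member of the ABA list, whose score was not computed without it. The ABA list score differed from WT by -0.57 in uap1-1 and -0.45 in uap1-2, with every mutant library under every WT library (two-sided exact permutation p = 0.0286, the smallest possible, and adjusted p = 0.458). The sugar and starch score was separated in the same way in both mutants (-0.26 and -0.33), as was the flavonoid score in uap1-1 (0.53, above WT), with the same p and adjusted p by that test.

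**Figure D5:**
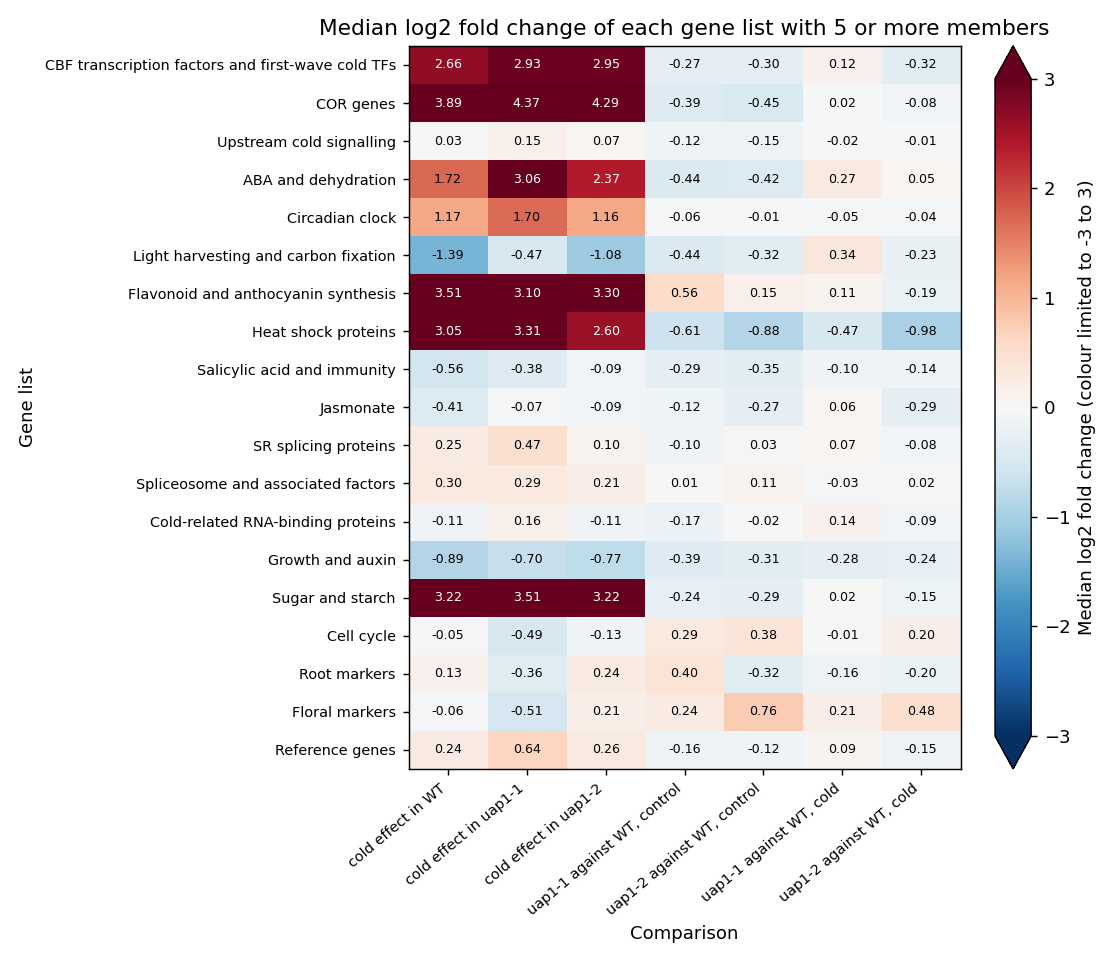
Median log2 fold change of each gene list with at least 5 measured members (vertical) in the cold effects and in the mutants against WT (horizontal); the printed values and colours give the median, with colour limited to -3 and 3. COR genes have medians of 3.89, 4.37 and 4.29 in the cold and -0.39 and -0.45 in uap1-1 and uap1-2 against WT under control conditions.

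In the cold, the CBF and COR genes named throughout did not differ detectably between the mutants and WT. Against WT, uap1-1 had log2 differences of 0.11 for CBF1 (95% interval -0.79 to 1.00), 0.06 for CBF2 (-0.83 to 0.95), 0.15 for CBF3 (-0.26 to 0.55), 0.02 for COR15A (-0.43 to 0.47), -0.07 for COR47 (-0.48 to 0.34), 0.03 for KIN1 (-0.47 to 0.52) and -0.13 for RD29A (-0.61 to 0.34). In uap1-2 they were -0.32 for CBF1 (-1.22 to 0.58), -0.36 for CBF2 (-1.26 to 0.53), -0.05 for CBF3 (-0.45 to 0.36), 0.09 for COR15A (-0.36 to 0.54), -0.25 for COR47 (-0.67 to 0.16), 0.09 for KIN1 (-0.40 to 0.59) and -0.21 for RD29A (-0.68 to 0.27). EdgeR called 0 genes for either mutant, with 580 and 1014 at an unadjusted p under 0.05 and smallest adjusted p of 0.969 and 0.928; DESeq2 also called 0 and 0. With the first within-group component as a covariate edgeR called 1 for uap1-1 (FIPS3) and 51 for uap1-2. Light-harvesting genes had a median of 0.34 in uap1-1, with 21 of 21 estimates positive, and -0.23 in uap1-2 (adjusted p = 0.779 and 0.536 with an estimated correlation). These were 0.18 without uap1-1 cold replicate 1, and -0.15, -0.08 and -0.13 without WT cold replicate 1 or 3 or uap1-2 cold replicate 4. Heat shock genes had a median of -0.98 in uap1-2, with 4 lower when adjusted over the list alone, and first-wave factors -0.32 with 0 of 13 positive (adjusted p = 0.329 and 0.536 with an estimated correlation). The heat shock score of uap1-2 cold replicate 2 lay apart at 2.94 (3.73 to 3.84 in the other 3), and without that library the median was -0.83 with 0 lower over the list alone and the score difference from WT -0.60 in place of -0.81. Without WT cold replicate 4 the median was -0.64 with 0 lower, and without WT cold replicate 3 it was -1.24 with 7 lower (adjusted p = 0.0154 with an estimated correlation). First-wave factors stood at -0.20, -0.51 and -0.21 without WT cold replicate 3, uap1-2 cold replicate 1 or uap1-2 cold replicate 2. With the preset correlation 4 lists passed in each mutant (2 to 5 and 1 to 10 with each library left out in turn), and with an estimated correlation 0.

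Whether the mutants responded to cold differently from WT was tested as the difference of the responses. EdgeR called 0 genes for uap1-1 and 0 for uap1-2, with 1842 and 371 at an unadjusted p under 0.05 and smallest adjusted p of 0.481 and 1. With the first within-group component as a covariate edgeR called 673 for uap1-1. DESeq2 called 1 gene for uap1-1, the ubiquitin ligase family gene ATL79 (log2 1.63, adjusted p = 0.028, Benjamini-Hochberg), and 0 for uap1-2. HAI1 rose by 3.99 on the log2 scale in uap1-1 and by 1.60 in WT, a difference of 2.39 (SE 0.56) with adjusted p = 0.481 by edgeR. With the covariate edgeR called this difference (2.39, adjusted p = 0.0225) and that of UGT78D4 (-1.19, adjusted p = 0.0116), which was not called without it. The median difference of light-harvesting genes was 0.80 in uap1-1 with 21 of 21 positive, and that of ABA genes 0.77 (7 higher and 1 lower when adjusted over the list alone), both with adjusted p = 0.455 with an estimated correlation. Light-harvesting genes stood at 0.51 without WT control replicate 1, and 1 to 14 ABA genes were higher over the list alone with each library left out in turn. In uap1-2 it was 0.46 for ABA genes, 0.29 for COR genes and -0.42 for flavonoid genes (adjusted p = 0.524, 0.255 and 0.202 with an estimated correlation). Without WT cold replicate 4 the ABA and COR values were 0.27 and 0.19, and COR genes stood at 0.16 without uap1-2 cold replicate 1 and 0.18 without WT control replicate 1. Flavonoid genes stood at -0.23 and -0.25 without WT control replicate 3 or 4, and passed without WT cold replicate 1 (adjusted p = 0.035 with an estimated correlation). SR genes stood at 0.18 in uap1-1 and -0.11 in uap1-2 (adjusted p = 0.455 and 0.696 with an estimated correlation), and at 0.11 in uap1-1 without uap1-1 cold replicate 1. With the preset correlation 9 and 5 lists passed (4 to 9 and 2 to 8 with each library left out in turn), and with an estimated correlation 0 and 0.

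The mutant lines were also compared with each other. Under control conditions edgeR called 2 genes, UGT78D4 and HAI1. Other fits called 7 (limma on quantile-normalized values), 8 (limma on log2(FPKM + 1)), 23 (DESeq2), 72 (limma on log2(FPKM + 5)) and 529 (library quality weights), and 1 with the replicate block. UGT78D4 (AT5G17040, chromosome 5, 5605201 to 5607128, minus strand), a flavonoid glycosyltransferase gene next to UGT78D3, was at 1.67 ± 0.504 CPM in uap1-1 and 0.474 ± 0.0734 CPM in uap1-2 (SD, n = 4), with WT at 0.76 ± 0.0984. Its log2 difference was -1.81 (SE 0.20, 95% interval -2.22 to -1.39, adjusted p = 0.000157), and that of HAI1 2.53 (SE 0.42, adjusted p = 0.0441), both by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the 31-base words of UGT78D4, 7.8% occur elsewhere in the genome. UGT78D4 stayed called in 8 of 8 fits that each left out a library. It was not called with the 8 libraries of the comparison alone (adjusted p = 0.288, edgeR), with limma on quantile-normalized values (-0.51, adjusted p = 0.185) or with limma on log2(FPKM + 5) (-0.21, adjusted p = 0.429). HAI1 did so in 1 of 8, without uap1-2 control replicate 2 (adjusted p = 0.0496), had adjusted p of 0.0979 to 0.407 in the other 7, and missed the threshold with library totals (adjusted p = 0.0615), median-ratio scaling (adjusted p = 0.055), the replicate block (adjusted p = 0.0546) and limma on log2(FPKM + 1) and log2(FPKM + 5) (adjusted p = 0.0534 and 0.16). Root markers were lower in uap1-2 by the median (-0.91) and SR genes higher (0.18, 19 of 20 positive), with adjusted p = 0.336 and 0.344 with an estimated correlation. In the cold, edgeR called 0 genes with 2368 at an unadjusted p under 0.05, and DESeq2 called 4 (FTSH10, FRS8, AT2G18300 and AT5G64270). Without uap1-1 cold replicate 2 edgeR called 6, and with the covariate 2520. A replicate block was put on these 8 libraries because deviations of same-numbered libraries correlated in these data, while no label gives a pairing. Its calls thus rest on a pairing taken from the same libraries. The block called 2222 genes, 1177 of them higher in uap1-2. Among these were HAI1, higher in uap1-2 in 4 of 4 pairs (log2 1.04, SE 0.17, adjusted p = 0.00504), and CBF2, lower in 4 of 4 (-0.50, SE 0.12, adjusted p = 0.0255), both by edgeR. With the block, 10 of 21 light-harvesting genes and 6 of 13 first-wave factors were lower in uap1-2 and 0 higher, each at adjusted p = 0.608 with an estimated correlation. Without it light-harvesting genes had a median of -0.56 with 0 of 21 positive (adjusted p = 0.362 with an estimated correlation).

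Last, genes that set both mutants apart from WT were sought. EdgeR called 0 genes in both mutants in either condition. At an unadjusted p under 0.05, 126 genes were higher and 303 lower in both under control conditions, and 59 and 23 in the cold. Both mutants were compared with the same WT libraries. In 20 simulations of unchanged groups, on average 138 were higher (109 to 164) and 96 lower (74 to 126) under control conditions. In the cold these were 120 (105 to 140) and 87.8 (70 to 109). Genes were drawn independently in all simulations of this paragraph, which leaves out variation that many genes share within a group. The simulated ranges may thus be too narrow, and no excess or shortfall was read from them. Independent lists would share 13.3, 43.8, 8.2 and 5.6. With the WT libraries split between the mutants in 6 ways, the observed lists shared on average 31.2 (27 to 38) and 59.7 (44 to 69) under control conditions and 8.5 (7 to 10) and 4.7 (4 to 5) in the cold, where independent lists of the same sizes would share 25.9, 42, 9.7 and 6.3. DESeq2 called 4 genes in both under control conditions (GAT1, AT3G06955, PSAA and NDHH) and 0 in the cold. Of these, PSAA and NDHH are chloroplast-encoded. Chloroplast-encoded genes took 0.0278% to 0.0627% of counts in WT control libraries, 0.0386% to 0.109% in uap1-1 control and 0.0386% to 0.107% in uap1-2 control. Whether PSAA and NDHH differed beyond that share was not tested. Across genes, the fold changes of the mutants against the shared WT libraries correlated at r = 0.477 under control conditions and 0.185 in the cold, against 0.508 and 0.496 for simulated unchanged groups. The covariances were 0.0568 and 0.0183 against simulated 0.052 and 0.051. With the WT libraries split between the mutants, r averaged -0.028 (6 splits, -0.237 to 0.241) and -0.171 (-0.393 to -0.003). With all mutant against all WT libraries, edgeR called 1 gene, with 1339 at an unadjusted p under 0.05, DESeq2 called 11 and edgeR with the covariate 14. The gene was AT3G06955 (chromosome 3, 16498192 to 16498394, minus strand, with no overlapping gene), at a log2 difference of 2.87 (SE 0.40, 95% interval 2.04 to 3.70, adjusted p = 0.00657, edgeR with Benjamini-Hochberg adjustment). It was at 0.274 ± 0.181 CPM in WT control, 2.26 ± 0.999 in uap1-1 control and 1.57 ± 0.76 in uap1-2 control, and at 0.0737 ± 0.0822, 0.754 ± 0.437 and 0.522 ± 0.176 CPM in the cold (SD, n = 4), from 0 to 12 counts per WT library and 5 to 89 per mutant library; uap1-2 control replicate 3, at 2.71 CPM, lay apart from its group. This contrast and AT3G06955 were chosen after the data had been seen.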

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

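All tests of regrouped libraries except that of all mutant against all WT libraries, and the tests of GC content, depth and the length trend at the pair of loci, were chosen only after the results they bear on had been seen; the other tests in this part were set before. Single libraries apart from their group were found in 19 of 216 groups of 4 values, where chance gives about 10.8.

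In WT cold, replicate 4 lay apart for CBF3 (75.5 CPM, nearest other 127), COR47 (8970, nearest 9210), RD29A (18700, nearest 14000) and the floral marker score (-0.53 mean log2 CPM, nearest 0.05). In uap1-1 control, replicate 2 lay apart for its TMM factor (0.986, nearest 1.21) and the reference gene score (7.55, nearest 7.11). In uap1-1 cold, replicate 2 had the highest total (25.5 M counts, nearest 19.8 M) and AT2G08735 at 0.373 CPM against 0 in the nearest, and replicate 1 the lowest scores of upstream cold signalling (4.77, nearest 5.02) and clock genes (6.74, nearest 7.23). In uap1-2 control, AT3G06955 was at 2.71 CPM in replicate 3 (nearest 1.28), AT2G08735 at 0 in replicate 1 (nearest 0.284) and the RNA-binding protein score at 6.56 in replicate 2 (nearest 6.67). In uap1-2 cold, replicate 1 had a TMM factor of 0.915 (nearest 0.977) and 8.26% of counts in its top 10 genes (nearest 7.53%), replicate 4 had RD29A at 15000 CPM (nearest 12500) and the seed marker score at 1.94 (nearest -0.62), and replicate 2 had the heat shock score at 2.94 (nearest 3.73). The seed marker score was -1.71 in WT control replicate 1 (nearest -2.74). Between the mutant lines under control conditions, UGT78D4 differed by -1.81 and HAI1 by 2.53 on the log2 scale, each by the test of that difference.

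For the cold effects, 1 of 35 splits of the 8 libraries, the real one, gave as many calls in WT, in uap1-1 and in uap1-2. The highest other split called 3363, 4081 and 763 genes against 11619, 11971 and 11245. These counts argue against chance as the cause. A share of 1 in 35 is the smallest these splits can give and was not adjusted, so the splits do not exclude chance. For uap1-1 against WT under control conditions 2 of 35 splits gave at least the 1 real call, and the other called 2172 genes, so chance cannot be excluded. Splits cannot test the 0 calls of uap1-2 against WT under control conditions or of both mutants against WT in the cold. The same holds for the 0 calls of the differences of response. Every split gives at least 0 calls, so 35 of 35 and 80 of 80 were fixed in advance. The highest other split called 344, 0 and 1 genes, and 4251 and 54 for the differences of response. Between the mutant lines, 1 of 35 splits, the real one, gave as many as the 2 control calls (highest other 0). That is the smallest share 35 splits can give, and it was not adjusted over the split tests. It is therefore weak evidence against chance for that count. It does not extend to each gene, since HAI1 was lost in 7 of 8 fits that left out a library. UGT78D4 was lost with the libraries of the comparison alone (adjusted p = 0.288, edgeR). In the cold, without the block, 35 of 35 was again fixed in advance by the 0 real calls (highest other 30, in a split that kept same-numbered libraries together). With the replicate block on these 8 libraries the real split called 2222 genes and the highest other of the 8 swaps within pairs 0, of which 1, the real one, gave as many; 8 swaps are too few for a share under 0.05. For all mutant against all WT libraries, 6 of 80 drawn splits gave as many as the 1 real call, with 1810 in the highest other, so chance cannot be excluded. For genes called in both mutants, 80 of 80 was likewise fixed by the 0 real calls in each condition, with a highest other of 0 and 0. Splits that called 2172, 4251 or 1810 genes point to a structure of the libraries other than genotype and condition.

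The first pattern weighed is a structure within groups. Whether it accounts for the splits that called many genes was not tested. Within groups, the first component of the residuals held 33.2% of the variance and the next 14.2%, and its gene loadings followed exonic length (Spearman rho 0.46 across genes, which are not independent). With each library's length trend removed the first component still held 28.6%, over 1.5 times the 14.9% of the next, which argues against transcript length as the whole cause. GC content is also argued against, with a partial rho of -0.13 given length, beside 0.48 for length given GC. Depth stays open: over 24 libraries the position on the axis had a Spearman rho of -0.35 with total counts (permutation p = 0.0961) and a Pearson r of -0.33 (p = 0.115), or -0.57 without the 2 libraries farthest from the median total. No biological explanation was tested, and differences between seedling batches or RNA preparations may underlie it.

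The second pattern is the lower ABA list score of both mutants under control conditions, -0.57 in uap1-1 and -0.45 in uap1-2, chosen from scores of which sugar and starch was as fully separated (-0.26 and -0.33). HAI1, the gene called for uap1-1 against WT, is a member of the ABA list, and the score was not computed without it. The call of HAI1 and this score are therefore not separate evidence. Leaving out each WT library in turn left at least -0.38, which argues against 1 WT library as the source of the size of the difference. It cannot test the separation, since leaving out a WT library cannot make separated groups overlap. Without uap1-1 control replicate 2 that line stood at -0.37. Removal of the length trend left -0.44, which argues against length. Scaling stays open: with library totals the smaller difference was -0.36 and a uap1-1 library overlapped WT, at -0.42. The genotype may be the cause, as a hypothesis, but with an estimated correlation the set missed the threshold in both mutants (adjusted p = 0.362 and 0.307), and the within-group structure is not excluded.

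The third pattern is a pair of loci, AT3G06955 and AT2G08735 (chromosome 2, 14907257 to 14907716, plus strand), for which all mutant libraries lay on one side of all WT libraries in each condition; 2 of 21428 genes did so, where chance gives 0.175. For AT2G08735 in the cold the gap was narrow, 0.373 CPM (9 counts) in uap1-1 replicate 2 against 0.383 CPM (8 counts) in WT replicate 2. The counts themselves had the reverse order, so that separation rests on how the libraries were scaled. None of the 31-base words of either locus occurs elsewhere in the genome (0%), which argues against reads of other copies. At their lengths (203 and 460 bases) the length trend of the libraries gave mutants 0.12 and 0.10 above WT on the log2 scale, against 2.87 and -2.77 observed, and with it removed the loci stood at 2.80 (adjusted p = 0.0086) and -2.89 (adjusted p = 0.0653; 0.0672 before, edgeR with Benjamini-Hochberg adjustment). This argues against length as the cause for either locus, although AT2G08735 passed the threshold in neither fit. A candidate explanation is a sequence or transcript difference at these loci between the mutant lines and the WT line, whether linked to UAP1 or not, which no table here tests.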

How the results depend on the processing

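The alternatives of DESeq2, limma on log2(FPKM + 1), library totals, DESeq2 size factors, the length trend, the covariate, the block on 8 libraries, the fit without 2 libraries, FPKM of at least 1 and the list tests without each library were chosen after seeing the data; the others were planned. Of 9261 values of single named genes, 9106 stayed on the same side of the threshold, 93 lost a call and 62 gained one. Of the values called in the main or the alternative fit, 0 changed direction. For values called in neither fit the direction was not compared. The cold counts stayed within 1.5 times under every alternative but the 2-fold threshold (6561, 6783 and 6227); where a count moved, the cause was not tested. At 19289385 to 25501547 counts per library, low genes such as AT3G06955 had 0 to 12 counts per WT library. Recovery of simulated changes was run at this depth alone.

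Calls of uap1-1 against WT under control conditions, 1 in the report, were 3 with FPKM of at least 5 (AT3G06955, UGT78D4 and HAI1). They were 325 with library quality weights, 14, 10 and 79 with limma on log2(FPKM + 1), + 0.1 and + 5, 3 with quantile normalization and 31 with DESeq2. They were 4 with library totals (AT3G06955, HY5, UGT78D4 and HAI1) and 3 with the length trend removed (UGT78D4, ATL79 and HAI1). They were 156 with the covariate and 2 without the 2 libraries farthest out (ATL79 and HAI1). The covariate was taken from the residuals of these libraries around their group means. It lowers the residual spread by construction, so counts obtained with it are no independent check. For uap1-2 they were 1 with quality weights and 1 with limma + 5 (AT2G01010), 13 with DESeq2 and 3 with the covariate (AT2G01010, GATL2 and DREB3). In the cold the covariate gave 1 for uap1-1 (FIPS3) and 51 for uap1-2. For the response of uap1-1, DESeq2 gave 1 (ATL79) and the covariate 673. Between the lines under control conditions, in place of 2, median-ratio scaling, the replicate block, library totals, the covariate and the fit without 2 libraries gave 1 (UGT78D4), the libraries of the comparison alone 1 (HAI1), quality weights 529, limma 8 and with + 5 72, quantile normalization 7 and DESeq2 23. In the cold the block on 8 libraries gave 2222, the covariate 2520 and DESeq2 4. For all mutant against all WT libraries, in place of 1, the replicate block gave 4 (AT2G01010, AT2G08735, AT3G06955 and HAI1), quality weights 5, limma 3, + 0.1 2 and + 5 3, quantile normalization 3, DESeq2 11, the covariate 14 and the fit without 2 libraries 2 (AT3G06955 and HAI1). In both mutants under control conditions, quality weights and limma + 5 gave 1 (AT2G01010), DESeq2 4 and the covariate 2 (AT2G01010 and GATL2). AT2G01010 is an rRNA gene with 96.5% of its 31-base words elsewhere in the genome. The replicate block moved no other count by over 1.5 times. Among named genes it ended the calls of HAI1 between the lines under control conditions (adjusted p = 0.0546), of RHD6 and AP1 for cold in uap1-1 (0.0508 and 0.0692) and of AT3G06955 for cold in WT (0.0578); 8 of the 24 libraries correlated best with those of their own number.

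Gene lists passing were 5, 5 and 5 in the cold effects, 0 and 2 for uap1-1 and uap1-2 under control conditions and 0 elsewhere with an estimated correlation, 3 with limma + 0.1 for the response of uap1-1, and with quantile normalization 3 for uap1-1 under control conditions, 2 for that response and 5 between the lines in the cold, against 12, 9 and 8. With library totals and limma on log2(FPKM + 1) the median log2 difference of all genes for uap1-1 against WT under control conditions was 0.125 and 0.112.

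With each library left out in turn, the calls ranged from 10723 to 11584 for cold in WT, 10879 to 11944 in uap1-1 and 10201 to 10801 in uap1-2, 1 to 2 for uap1-1 and 0 to 1 for uap1-2 against WT under control conditions, 0 to 0 for both in the cold, 0 to 2 and 0 to 0 for the responses, 1 to 2 and 0 to 6 between the lines in control and cold, 1 to 2 for all mutants, and 0 to 1 and 0 to 0 for both mutants in control and cold. Single libraries decided these: AT3G23510 was added without WT control 3, ATL79 without uap1-1 control 2 (with OFUT7 for the response), UGT78D4 without uap1-1 control 4, CCX1 (and AT4G20000 between the lines) without uap1-2 control 3, and 6 calls between the lines in the cold without uap1-1 cold 2. For all mutants, HAI1 was added without WT cold 4 or uap1-1 cold 4, AT2G08735 without uap1-1 cold 2 or uap1-1 control 2, and AT2G01010 without uap1-1 cold 1. HAI1 stayed called in 8 of 8 such fits for uap1-1 against WT, with adjusted p of 0.000785 to 0.0224 over all fits with edgeR, and was called by DESeq2 and limma too, and AT3G06955 in 24 of 24 for all mutants.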

Other observations

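The KEGG pathway tests in this part were chosen after the data had been seen, and 122 pathways were tested per comparison. In the cold, genes of ribosome biogenesis, which build the ribosomal subunits, rose in WT in 66 of 95 cases and fell in 3 (camera adjusted p = 6.3e-11; adjusted p = 0.53 with an estimated correlation), in uap1-1 in 50 and fell in 6, and in uap1-2 in 63 and fell in 3. Genes of the proteasome, the protease that degrades ubiquitin-tagged proteins, rose in WT in 33 of 65 cases and fell in 1, in uap1-1 in 38 and fell in 4, and in uap1-2 in 32 and fell in 1. Of 197 spliceosome pathway genes, 91 rose and 30 fell in WT (camera adjusted p = 0.00193; adjusted p = 0.565 with an estimated correlation), 87 and 28 in uap1-1, and 80 and 30 in uap1-2. RNA transport had 87 of 177 genes up and 26 down in WT, and carotenoid synthesis 14 of 27 up and 4 down.

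Pathways with more genes down were GPI-anchor synthesis, which makes the lipid anchors of surface proteins, with 20 of 27 lower and 0 higher in WT, 20 and 0 in uap1-1 and 16 and 0 in uap1-2, and glucosinolate synthesis, which makes defence compounds, with 16 of 22 lower and 2 higher in WT, 16 and 2 in uap1-1 and 14 and 2 in uap1-2. Photosynthesis genes fell in 40 of 74 cases in WT, 27 in uap1-1 and 52 in uap1-2, and rose in 3, 7 and 2. Across the pathways, 8 passed upward and 8 downward in WT, 7 and 7 in uap1-1, and 7 and 7 in uap1-2 with the preset correlation, and 0 with an estimated correlation in each. Under control conditions the 336 ribosome genes had a median log2 difference of 0.13 in uap1-1 and 0.22 in uap1-2 against WT, with adjusted p = 0.99 and 0.491 with an estimated correlation.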
